A study of Homo sapiens with 4 samples.

How the data were processed

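Gene expression was measured in 4 EpiDerm FT tissues, a full-thickness human skin model in which a stratified keratinocyte epidermis is grown on a fibroblast dermis. Per the labels' protocols, tissues were equilibrated for 5 hours and then received 25 µl of test material on the surface for 24 hours, in duplicate. The test material was acetyl zingerone (AZ), an analog of the ginger compound zingerone, at 50 µg/ml. Per the labels, AZ was prepared as a 20 mg/ml stock in DMSO and brought to its final strength with water. The labels name the control (CTL) as water in the text on the series and as the solvent in the treatment protocol, so the DMSO content of the controls stays unsettled. The 2 CTL and 2 AZ tissues were taken as replicates. The labels call them duplicates of bought tissues and do not say whether they came from separate batches of culture, so p-values measure only the spread between these 4 samples, which may be technical.

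Each sample was labelled with Cy3, from 0.6 µg of RNA per the labels, and hybridised to 1 single-colour Agilent array of 62976 spots. The deposited scanner files hold spot intensity on a linear scale, processed within each array by Feature Extraction 10.7.3.1 (background subtraction and spatial detrending), per the file headers. The deposited value table holds log2 values of the same arrays. The submitters' processing notes name limma for it, and neither its background step nor its normalization is given in the sources used here. Its medians were 5.26, 5.25, 5.25 and 5.26 for CTL 1, CTL 2, AZ 1 and AZ 2. Its correlation with the log2 scanner intensity of the same array was 0.987 to 0.990 across probes, and differences between arrays ran the same way in both (r = 0.928 to 0.962 across probes), so its log2 scale and direction were settled and it was not centred per gene. Its between-array method stays unknown.

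From the scanner files, the log2 processed signal was scaled by subtracting each array's 75th percentile over the 50599 non-control probes, so all levels are log2 values relative to that percentile. Control spots and spots marked as outliers (483 to 535 per array) were left out, and spots of the same probe were averaged. No spot was saturated. Gene symbols came from matching the RefSeq transcript accession on the array, without version, to a RefSeq gene table of the GRCh38.p14 assembly. Of the non-control probes, 30275 were named in this way and 20324 were not. The files use another genome build than that table, so no coordinates are given. The 96 probes for XIST and chromosome Y genes were left out. A probe was tested if the scanner software marked it well above background on at least 2 of the 4 arrays, which kept 30734 probes, 22644 of them named. Each gene was represented by its brightest tested probe, which gave 16722 genes. A gene not well above background on either array of a group has only a bound there. Its fold is given as "at least", from the mean of the brighter group against the mean over the dim group's arrays of the lowest signal that was well above background, or of the gene's own signal if higher.

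AZ was compared with CTL by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. A total of 38 gene lists was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and beside it with an estimated correlation and with fry. With an estimated correlation, camera rests on the residual degrees of freedom of the 4 arrays, 2 here. A list can hardly pass it then, so its adjusted p says little about correlation between genes. They cover extracellular matrix (a matrisome list, which joins the collagens, proteoglycans and extracellular matrix glycoproteins, and a matrix cross-linking list), metalloproteinases, protease inhibitors, hyaluronan, inflammation (IL-17A-induced genes, cytokines and chemokines), redox and xenobiotic responses, the layers of the epidermis, other cell types (fibroblast, melanocyte, endothelial, leukocyte), and stress, signalling and housekeeping pathways. The lists held 1243 distinct genes, with 4 symbols updated to current ones. A further 2 listed symbols were dropped, as matching no gene of the table or repeating a gene listed under an updated symbol. A list's level is the mean of its tested genes relative to the CTL mean, and its shift is the mean log2 fold change of its genes minus that of all other genes. The design, the lists, the rule for named genes and the alternatives, except those named as added later, were fixed before the data were examined. Genes are named by that rule: the 6 genes with the smallest p in each direction where none passes, up to 4 members with the smallest p and the brightest member of each list described, and 28 genes fixed by name.

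All 4 arrays had between 57.7% and 62.2% of probes well above background, and their number limits the precision. The median standard error of a log2 fold change was 0.22. The tests were checked on simulated data with 16722 genes and the spread estimated for this comparison. In 20 runs, limma recovered on average 0.448% of genes changed 2-fold, 46.1% of those changed 4-fold and 84.1% of those changed 8-fold, with 5.15 false calls per run. A list of 50 genes shifted by 0.5 was called in 20 runs and a null list in 1 run, in simulations that held no correlation between genes. Alternatives covered the normalization, background correction, dim-probe filter, probe rule, variance model, threshold, a replicate block, leaving out each replicate and the authors' value table. Both CTL arrays lay on 1 slide and scan and both AZ arrays on another, so batch and group cannot be told apart and a slide block could not be fitted.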

Results

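Messenger RNA levels were measured on single-colour arrays in 4 full-thickness reconstructed human skin tissues, 2 treated for 24 hours with 50 µg/ml acetyl zingerone (AZ) and 2 control tissues (CTL). The study set out to see what AZ does to matrisome genes, matrix metalloproteinases and targets of the cytokine IL-17A. Of 50599 probes, 29184 and 29892 were well above background in CTL replicates 1 and 2, and 31477 and 30509 in AZ replicates 1 and 2. The standard deviation of log2 differences between arrays over the tested probes was 0.44 between the CTL arrays, 0.62 between the AZ arrays and 0.53 to 0.75 between arrays of different groups, so the AZ tissues differed from each other more than the CTL tissues did. AZ replicate 1 differed less from CTL replicates 1 and 2 (0.59 and 0.53) than from AZ replicate 2.

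Across all genes, the most clearly separated levels belonged to genes of varied function. ZNF467, a zinc finger protein gene, had a level of 3.47 ± 0.19 in CTL and 5.68 ± 0.13 in AZ (log2, SD, n = 2 each), although its other tested probe had a log2 fold change of 0.31. UNCX, a homeobox gene, had 6.15 ± 0.18 in CTL and 3.89 ± 0.11 in AZ, and RNU2-1, a U2 spliceosomal RNA, had 3.16 ± 0.00 and 1.14 ± 0.24. The small nucleolar RNA SNORD84 had a log2 fold change of -1.84, AVP, which encodes the vasopressin precursor, one of -1.77, and the uncharacterised LOC101927769 one of 2.22. The other genes with the smallest p were not well above background in 1 group. PRSS50 was measured at least 2.48-fold and LOC157273 at least 2.44-fold lower in AZ, while MUC5B, SLC9A3, LINC01349 and ECEL1 were at least 1.89-fold, 2.63-fold, 4.51-fold and 2.09-fold higher. None of these differences passed the test. By limma, 0 of 16722 genes had an adjusted p under 0.05, the smallest adjusted p being 0.164, and limma with a trended, robust variance also gave 0. At an unadjusted p under 0.05 there were 2079 genes, 1216 higher and 863 lower in AZ, where 836 would be expected by chance. Of the 2079, 701 were among the 3345 dimmest genes and 291 among the 3345 brightest. The dimmest genes also leaned upward, with 60.2% of the 3345 higher in AZ, against 53.2% to 54.5% in brighter groups of like size. With median scaling, the genes at that p split into 862 higher and 1118 lower. The 2 groups did not overlap for 50.1% of genes, against 33.3% by chance, and 890 genes were also at least 2-fold apart, 364 higher and 526 lower in AZ. The smallest p that 2 against 2 samples can give in an exact permutation test is 0.333. Without AZ replicate 1, limma called 752 genes, 122 higher and 630 lower in AZ replicate 2, a fit in which the lone AZ tissue is assumed to vary like the controls. At an unadjusted p under 0.05 that fit had 4543 genes, against 1934 without AZ replicate 2 (0 called), 723 without CTL replicate 1 and 919 without CTL replicate 2. The CTL arrays lay on 1 slide and the AZ arrays on another, so slide and group cannot be told apart in any difference given here.

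Genes of the extracellular matrix and of dermal fibroblasts rose together in both AZ tissues. The 150 matrisome genes tested had a mean level of 0.37 ± 0.10 relative to the controls (log2, SD, n = 2), a 1.29-fold rise, with 0.30 in AZ replicate 1, 0.44 in AZ replicate 2 and -0.13 and 0.13 in the controls. Of these genes 129 were higher and 21 lower in AZ, and the groups did not overlap for 83 of the higher and 10 of the lower ones. The rise of the list passed limma's camera (adjusted p = 2.17e-07), and it had adjusted p = 0.779 with an estimated correlation. COL1A1, the main collagen of the dermis, had a log2 fold change of 0.66 (95% interval 0.19 to 1.13), COL3A1 0.80 (0.08 to 1.52), COL6A3 0.84 (0.26 to 1.43) and ELN, which encodes elastin, 0.92 (0.16 to 1.69). The calcification inhibitor MGP had 1.22 (0.38 to 2.06), the matricellular protein CCN3 0.96 and the latent TGF-beta binding protein LTBP2 0.70. Intervals that included 0 were found for COL1A2 (0.36), FN1, the fibronectin gene (0.52), and the small leucine-rich proteoglycans DCN (0.36) and LUM (0.38). The dim collagens COL26A1 and COL20A1 had 0.84 and 0.85. No matrisome gene passed limma over all genes or adjusted over the list alone.

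**Figure D1:**
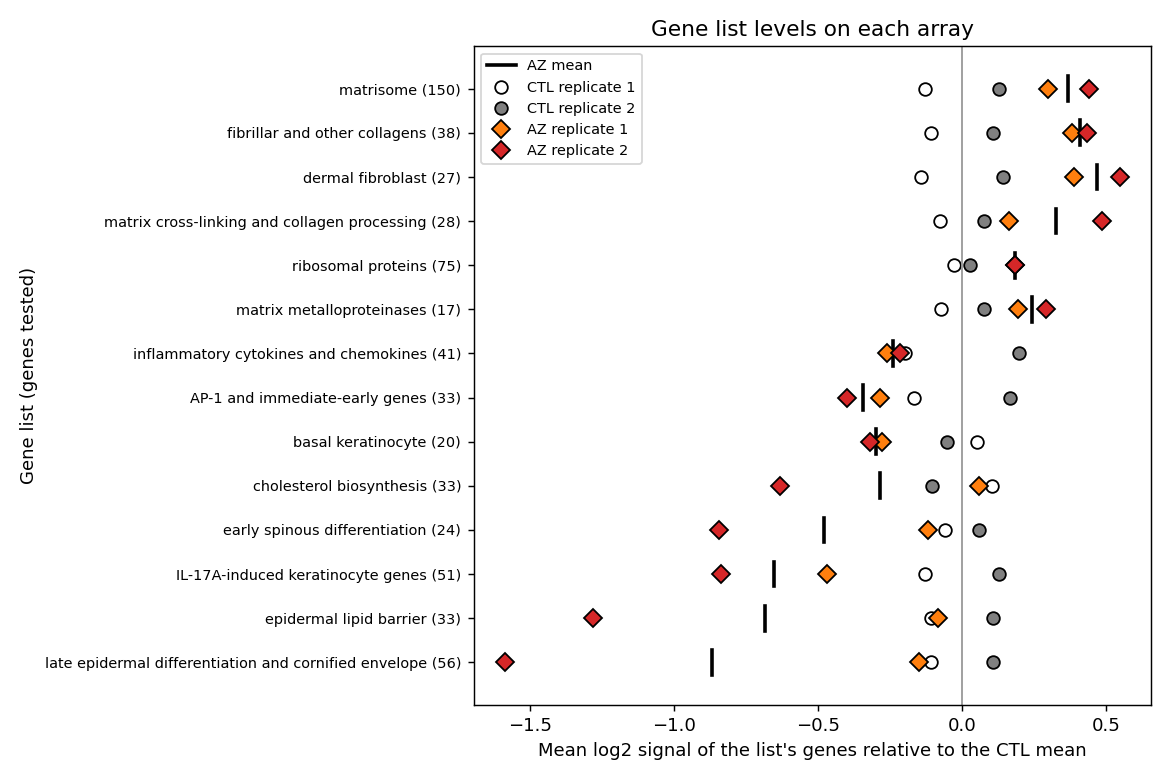
Mean log2 signal of the genes of 14 lists on each array, relative to the mean of the 2 CTL arrays (x axis), with the number of genes tested after each list's name; circles are CTL arrays, diamonds AZ arrays, and the bar is the AZ mean. Both AZ tissues lay above both controls for the matrisome list (0.30 and 0.44) and below them for the IL-17A-induced list (-0.47 and -0.84), while late differentiation genes lay at -0.15 in AZ replicate 1 and -1.59 in AZ replicate 2; for ribosomal proteins the AZ symbols coincide.

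By class, 32 of 38 collagens (mean log2 fold change 0.41), 21 of 23 proteoglycans (0.33) and 76 of 89 matrix glycoproteins (0.36) were higher in AZ, with camera adjusted p = 0.000434, 0.00867 and 5.12e-06. Each class rose, and each had adjusted p = 0.779 with an estimated correlation. Proteoglycans also held genes with values the other way, such as NYX (1.77 ± 0.17 in the controls against 1.13 and 0.41 in the AZ tissues) and the testican SPOCK2 (-0.69, with 1.28 at its other probe), beside VCAN, which encodes versican (0.70). PRG3 was at least 1.49-fold higher in AZ. In the glycoprotein class the laminin chain LAMA4 had 0.79 and the abundant IGFBP2 0.21. The 28 genes of collagen cross-linking and processing rose (mean log2 fold change 0.32, 26 higher, adjusted p = 0.00154, and 0.789 with an estimated correlation). Among them were the procollagen chaperone FKBP10 (0.77), the procollagen C-proteinase enhancer PCOLCE (0.80), the prolyl hydroxylase P3H1 (0.76), BMP1 (0.51) and P4HB (0.07, with -0.10 at its other probe). All 27 dermal fibroblast markers were higher in AZ, by a mean of 0.47 (adjusted p = 5.12e-06, and 0.779 with an estimated correlation), among them the intermediate filament gene VIM (0.72), and 14 of them belong to other lists too. Basal keratinocyte markers fell beside them, as given below. None of the genes of these lists passed adjusted over the list alone. Without CTL replicate 1 the shift of the matrisome list against all other genes went from 0.35 to 0.23 and that of the glycoproteins from 0.35 to 0.22, without AZ replicate 2 the cross-linking list was no longer called (0.12, against 0.31 with all tissues and 0.49 without AZ replicate 1), and the proteoglycans were not called without CTL replicate 1 (0.19), without AZ replicate 2 (0.22) or with no filter on dim probes (0.12).

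Matrix metalloproteinases, the enzymes that degrade matrix, showed no common direction that passed the test. Of 17 tested, 13 were higher and 4 lower in AZ, with a mean level of 0.24 ± 0.07 (log2, SD, n = 2) and camera adjusted p = 0.113 (0.779 with an estimated correlation). MMP3 (stromelysin 1) was the furthest down, with a log2 fold change of -1.49 (95% interval -2.53 to -0.45) and levels of 3.60 and 2.48 in the AZ tissues against 4.53 ± 0.23 in the controls. The interstitial collagenase MMP1 was the brightest and had 0.07 (-0.42 to 0.56). MMP23B had 1.18 (0.38 to 1.98), MMP17 0.72 (0.16 to 1.28), the membrane-bound MMP14 0.69 (-0.05 to 1.42), MMP2 0.38, MMP9 0.45, MMP10 0.47 and MMP12 -0.06, the last 4 with intervals that included 0. No metalloproteinase passed limma over all genes or adjusted over the list alone. Of 20 protease inhibitors, 10 were higher and 10 lower (mean -0.18, adjusted p = 0.458). TIMP1 had 0.57 and TIMP2 0.46, with adjusted p = 0.415 and 0.452 by limma, SERPINF1 0.63, the plasminogen activator inhibitor SERPINB2 -1.12, SERPINA1 -1.77 and the elastase inhibitor PI3 -0.88. In hyaluronan metabolism 7 of 14 genes were higher, with a mean of -0.06, a median of 0.08 and a camera direction of down (adjusted p = 0.835). The hyaluronan synthase HAS2 had 0.36 and HAS3 -0.80, the hyaluronan receptor CD44 0.52, UGDH 0.73 and HYAL4 -0.71. None of these passed adjusted over the list alone. With normexp background correction and 75th percentile scaling, the metalloproteinase list was called higher (shift 0.25, adjusted p = 0.0191).

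**Figure D2:**
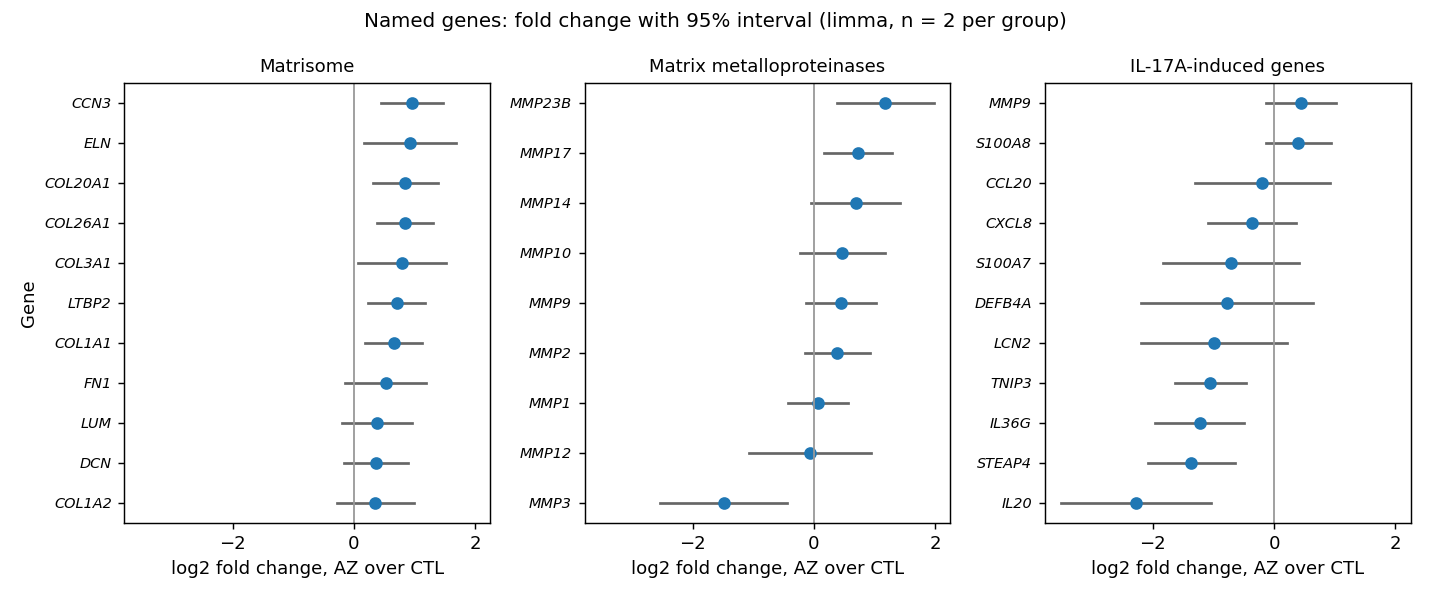
Log2 fold change of AZ over CTL (x axis) for genes named from the matrisome, metalloproteinase and IL-17A-induced lists, with points for the estimates and lines for limma's 95% intervals (n = 2 per group). The interval lay above 0 for COL1A1 (0.66), below 0 for MMP3 (-1.49) and IL36G (-1.23), and included 0 for MMP1 (0.07) and S100A8 (0.40); no gene shown passed the threshold on the adjusted p.

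Genes that IL-17A induces in keratinocytes were lower in both AZ tissues. The treatments described were AZ or control alone. These are thus levels without added IL-17A, and a response to it was not measured. The 51 tested had a mean level of -0.65 ± 0.26 (log2, SD, n = 2), which is 1.57-fold lower than in the controls, with -0.47 in AZ replicate 1, -0.84 in AZ replicate 2 and -0.13 and 0.13 in the controls. Of these 44 were lower and 7 higher in AZ, and the groups did not overlap for 29 of the lower and 3 of the higher ones. The fall passed limma's camera (adjusted p = 3.36e-08), and it had adjusted p = 0.779 with an estimated correlation. The basal keratinocyte list was lower too, with means of -0.28 and -0.32 in AZ replicates 1 and 2, as given below. The metalloreductase STEAP4 had a log2 fold change of -1.36 (95% interval -2.08 to -0.64), the epidermal cytokine IL36G -1.23 (-1.96 to -0.50), TNIP3, an interactor of the NF-kappaB regulator A20, -1.05, and IL20, which was well above background in 1 of the 2 AZ tissues, -2.27. The antimicrobial genes LCN2 (-0.99), DEFB4A (-0.78) and S100A7 (-0.71) had intervals that included 0. LCN2 had 5.85 ± 0.09 in the controls against 5.54 and 4.17 in the AZ tissues. DEFB4A had 8.86 and 8.26 in the controls against 8.56 in AZ replicate 1 and 7.01 in AZ replicate 2. S100A7 had 9.32 ± 0.03 against 9.24 and 7.97, so both were low mainly in AZ replicate 2. DEFB4A and S100A7 have near-identical copies that their probes may also detect. The neutrophil chemoattractant CXCL8 had -0.36 and the chemokine CCL20 -0.20. S100A8, the brightest of the list, ran the other way with 0.40. Of the 55 genes listed, 14 belong to other lists, and no gene passed limma over all genes or adjusted over the list alone. Late differentiation markers were low in AZ replicate 2, as given below, and without that tissue the list's shift against all other genes was -0.51 in place of -0.67 (adjusted p = 6.31e-08). Inflammatory cytokines and chemokines also fell (mean log2 fold change -0.24, 26 of 41 lower, adjusted p = 0.0176, and 0.789 with an estimated correlation), with CCL8 at -1.36, CSF2 at -1.20, CCL7 at -0.89, CXCL14 at 0.66 and CXCL1 at -0.03 (0.23 at its other probe). That list was no longer called without CTL replicate 2 (-0.06), without AZ replicate 1 (-0.21), with no filter on dim probes (-0.20), with the mean of a gene's probes (-0.20) or with probes taken singly (-0.06), and its shift went from -0.26 to -0.45 without CTL replicate 1.

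In their list means, genes of the upper epidermis were low in AZ replicate 2 and close to the controls in AZ replicate 1. Late differentiation and cornified envelope genes fell (mean log2 fold change -0.87, 54 of 56 lower, adjusted p = 9.58e-11, and 0.779 with an estimated correlation), with -0.15 in AZ replicate 1 against -1.59 in AZ replicate 2. The shift against all other genes was -0.89, and it was -0.20 without AZ replicate 2 (adjusted p = 0.0245) and -1.58 without AZ replicate 1. FLG, the filaggrin gene, had 5.95 ± 0.02 in the controls and 5.93 and 4.24 in the AZ tissues, and LORICRIN had 8.91 ± 0.06 against 8.88 and 7.27. PADI1, a peptidylarginine deiminase of cornification, was alike in both AZ tissues (0.87 and 0.90, against 1.79 ± 0.08 in the controls). TCHH had -1.04, SERPINB12 -1.55, CRCT1 -1.08 and SPRR2E -0.25. TCHH was low in both AZ tissues (1.77 and 1.12, against 2.48 ± 0.19 in the controls). The same held for SERPINB12 (-3.56 and -4.81, against -2.63 ± 0.14). SPRR2E was not low in AZ replicate 1 (10.17 and 9.46, against 10.07 ± 0.10). Genes of the lipid barrier fell (mean log2 fold change -0.68, 29 of 33 lower, adjusted p = 7.23e-06, and 0.789 with an estimated correlation), among them the ceramide glucosyltransferase UGCG (-0.99), PNPLA1 (-1.32), DEGS2 (-0.81) and NIPAL4 (-0.99), with STS at 0.89. Spinous genes fell (mean log2 fold change -0.48, 21 of 24 lower, adjusted p = 4.39e-05, and 0.779 with an estimated correlation). Among them were the desmosomal cadherins DSC2 (-1.01) and DSG3 (-0.83), and PRDM1 (-0.80). These were low in both AZ tissues. DSC2 had 2.01 and 1.70 there against 2.86 ± 0.17 in the controls, DSG3 4.75 and 4.43 against 5.42 ± 0.14, and PRDM1 3.24 and 2.98 against 3.91 ± 0.32. KRT10 (0.21) and NOTCH1 ran the other way. NOTCH1 had 0.47 ± 0.18 in the controls against 2.51 and 1.44 in the AZ tissues, but a log2 fold change of -0.89 at its other probe. Without AZ replicate 2 the lipid barrier (shift -0.13, in place of -0.70) and spinous lists (-0.16, in place of -0.50) were no longer called, and without AZ replicate 1 their shifts were -1.28 and -0.84. The mean of the basal keratinocyte genes fell alike in both AZ tissues, by -0.28 and -0.32 (15 of 20 lower, adjusted p = 0.00867, and 0.779 with an estimated correlation). JAG2 had -1.05, SOX9 -0.89, the hemidesmosomal integrin ITGB4 -0.81 and DST -0.68 (0.17 at another of its probes). KRT14, the brightest member, had -0.34 and was not low in AZ replicate 1. Its levels were 9.07 there and 8.29 in AZ replicate 2, against 9.02 ± 0.00 in the controls. That list was not called without AZ replicate 1 (-0.31, adjusted p = 0.0795). Keratins and partners of wounded epidermis were not called (mean -0.10, adjusted p = 0.447), with HBEGF at -0.91, GJB6 at -1.14, KRT6A at -0.18, and TGFA at 0.62 (-1.56 at its other probe), but without AZ replicate 1 they were called lower (shift -0.31, adjusted p = 0.0279), and without AZ replicate 2 the shift was 0.075, not called. No gene of these 5 lists passed adjusted over the list alone.

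Among signalling and housekeeping groups, AP-1 and immediate-early genes fell (mean log2 fold change -0.34, 26 of 33 lower, adjusted p = 0.000261, and 0.779 with an estimated correlation). FOS had -1.13, FOSB -0.74, EGR3 -1.81, IER3 -0.98 and CCN1 0.24, and the call was lost without CTL replicate 2 (shift -0.20). Cholesterol synthesis genes fell (mean log2 fold change -0.29, 26 of 33 lower, adjusted p = 0.00867, and 0.833 with an estimated correlation), with FDFT1 at -0.77, SCD at -0.48, MSMO1 at -0.86 and FDPS at -0.45. The cholesterol list lay at 0.06 in AZ replicate 1 and -0.63 in AZ replicate 2, and it was not called without AZ replicate 2 (shift 0.015) or without CTL replicate 1 (-0.19), the shift being -0.30 with all tissues and -0.62 without AZ replicate 1. Heat shock genes fell (mean log2 fold change -0.26, 18 of 24 lower, adjusted p = 0.0214, and 0.779 with an estimated correlation), with HSPA6 at -1.01 (0.27 at its other probe) and HSPB1 at -0.30, and were not called without AZ replicate 2 (shift -0.08) or with no filter on dim probes (-0.27). Without AZ replicate 1 their shift was -0.48, against -0.28 with all tissues. Ribosomal protein genes rose (mean log2 fold change 0.18, 62 of 75 higher, adjusted p = 0.00154, and 0.779 with an estimated correlation), led by RPS12 (0.91), with RPL14 at 0.51, RPL17 at 0.54 (-0.42 at the lowest of its 4 probes) and RPS2 at 0.27. That call was lost with quantile normalization (shift 0.08), with normexp and quantile normalization (0.08) and with the authors' value table (0.06). None of these genes passed adjusted over the list alone.

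Redox and xenobiotic response genes showed no shift that passed the test. NRF2 targets had a mean of -0.04 (17 of 36 higher, adjusted p = 0.562). HMOX1, heme oxygenase 1, had a log2 fold change of -0.99 (95% interval -1.66 to -0.33), GCLM, the modifier subunit of glutathione synthesis, -0.80, CES1 -0.75, NQO1 0.50, GSR 0.52 (-0.23 at its other probe) and the ferritin heavy chain FTH1 0.54. Other antioxidant enzymes had a mean of 0.07 (23 of 36 higher, adjusted p = 0.308), with SESN3 at 0.70, GPX4 at 0.55, MGST3 at 0.46 and GPX1 at 0.42. The metallothionein list had a mean of -0.22 and a median of 0.03 (7 of 13 higher, camera down, adjusted p = 0.375). Its abundant members MT2A (0.47) and MT1X (0.55) opposed the dim MT1H (-0.73) and MT4, which was at least 2.20-fold lower in AZ and was the 1 gene of the list past the threshold adjusted over the list alone. Aryl hydrocarbon receptor targets had a mean of -0.20 (adjusted p = 0.251), with LRAT at -0.97, SLC7A5 at -1.16 and CYP1B1 at 0.66.

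Of the remaining lists none was called with all 4 tissues. Melanocyte (mean 0.20, adjusted p = 0.352), endothelial (0.09, 0.562) and leukocyte genes (0.14, 0.545) had no shift past the threshold. The model is described as keratinocytes on fibroblasts, and 10 of 16, 9 of 16 and 20 of 32 genes were tested. These 3 lists thus say little about such cells. The same held for cell cycle (0.11, 0.418), histone (-0.10, 0.139), p53 target (0.05, 0.901), type I interferon (-0.06, 0.545), TGF-beta target (0.19, 0.226) and proteasome genes (-0.08, 0.223). Several of these were called when 1 tissue was left out. Cell cycle genes were higher without CTL replicate 1 (shift 0.31) and without AZ replicate 2 (0.25), but had shifts of -0.13 without CTL replicate 2 and -0.065 without AZ replicate 1, which were not called. Without CTL replicate 2, TGF-beta targets were higher (0.32, against 0.17 with all tissues and 0.015 without CTL replicate 1) and interferon genes lower (-0.24), the latter with 0.084 without CTL replicate 1 and 0.085 without AZ replicate 2, not called. Histone (-0.32) and proteasome genes (-0.26) were lower without AZ replicate 1 and had 0.080 and 0.060 without AZ replicate 2, not called. In hypoxia and glycolysis the mean was 0.04, the median -0.01 and the camera direction down (adjusted p = 0.871). In that list PFKL (1.61, 95% interval 0.94 to 2.29) and the lactate exporter SLC16A3 (1.11, 0.64 to 1.58) were the 2 genes past the threshold adjusted over the list alone, while HK2 had -1.04 and ENO1 0.44, and without AZ replicate 2 the list was called lower (shift -0.18, adjusted p = 0.0303). Signs also differed between mean, median and test for the unfolded protein response (mean 0.01, camera down, adjusted p = 0.835), oxidative phosphorylation (mean 0.01, median -0.01, down, 0.811), retinoid (mean -0.08, median 0.10, down, 0.765) and apoptosis genes (mean -0.08, median 0.05, down, 0.375). Of the 38 lists, 16 were called by camera, 7 up and 9 down, 0 with an estimated correlation (smallest adjusted p = 0.779) and 0 by fry (smallest adjusted p = 0.261). The version with an estimated correlation had 2 degrees of freedom and could hardly call a list.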

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

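Added after the data were seen were the normexp fits on the median signal (those planned on the mean signal were not run, since that column is not in the scanner files), the crossed pairing and the lists without shared members; a slide block could not be fitted. The count of 0 genes held under the other normalizations, backgrounds, filters, probe rules, thresholds and variance model tried, with 1951 to 2756 genes or probes at an unadjusted p under 0.05. With the replicate number as a block it was also 0 (1727 at an unadjusted p under 0.05). Same-numbered arrays did not deviate together (r = -0.134 across genes), and the crossed pairing called 40 genes, 19 higher and 21 lower, the cause of which was not tested. Leaving out 1 replicate gave 0 to 752 genes; the high count came without AZ replicate 1, while without AZ replicate 2, where the same 2 controls give the spread, it was 0, and the cause was not tested. With the block, the matrisome (0.35), metalloproteinase (0.22) and IL-17A-induced lists (-0.67) kept their side of the threshold. In this balanced design a block cannot change the shifts themselves. The trended, robust variance model does not enter camera, so list results under it repeat the main fit. Leaving out a replicate gave 0.23 to 0.48 for the matrisome list, 0.15 to 0.30 for metalloproteinases and -0.83 to -0.51 for IL-17A-induced genes, with no call gained or lost. With an estimated inter-gene correlation, the matrisome (0.35) and IL-17A-induced (-0.67) shifts were not called by camera (adjusted p = 0.779). Their estimated correlations were 0.22 and 0.15, against the preset 0.01. Metalloproteinases (0.00066) and basal keratinocyte genes (-0.032) had estimates under the preset. Their unadjusted camera p still went from 0.051 to 0.17 and from 0.0029 to 0.083. A higher correlation was thus not the cause for these lists. With an estimated correlation, camera also takes the 2 residual degrees of freedom of the 4 arrays in place of a number set by the genes. That raises p by itself. The metalloproteinase shift was called with normexp and the 75th percentile (0.25, adjusted p = 0.0191, against 0.0602 to 0.226 in the other settings that kept all replicates and the preset correlation), and the cause was not tested. Without members of the dermal fibroblast list the matrisome shift was 0.34, and without members of other lists the IL-17A-induced shift was -0.78 and the metalloproteinase shift 0.20. Of the 16 called lists, 0 kept their call with an estimated correlation, 13 to 16 under each other setting that kept all replicates and covered all lists, 14 without CTL replicate 1, CTL replicate 2 or AZ replicate 1, and 10 without AZ replicate 2. Leaving out a replicate gave cholesterol shifts of -0.62 to 0.015 and hypoxia and glycolysis shifts of -0.18 to 0.21. Without AZ replicate 2, the cholesterol shift turned to 0.015 (adjusted p = 0.693) and the hypoxia and glycolysis shift to -0.18 (adjusted p = 0.0303), as that tissue lay at -0.63 and 0.20 on these lists and AZ replicate 1 at 0.06 and -0.13. Of 200 named genes, 20 changed sign in some setting and 3 of those had an unadjusted p under 0.05. Dim signal was a limit: in the 3345 dimmest genes the median log2 fold change was 0.136, against 0.0278 to 0.0461 in 4 brighter groups of like size.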

Other observations

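Families of genes that share a symbol were formed after the values were seen, and 13 of 62 were called by limma's camera, 0 with an estimated correlation (smallest adjusted p = 0.838). Small nucleolar RNAs, which guide the modification of ribosomal RNA, were low: 69 of 90 SNORA genes (mean log2 fold change -0.34, adjusted p = 4.68e-07) and 116 of 167 SNORD genes (-0.25, adjusted p = 9.5e-07). Their levels differed within each group, with SNORD genes at 0.20 and -0.20 in the controls and -0.51 and 0.01 in AZ replicates 1 and 2. Kallikrein proteases (KLK, 12 of 14 lower, mean -0.74) and SERPINB inhibitors (11 of 12 lower, -0.77), both abundant in the upper epidermis, lay at -0.07 and -0.29 in AZ replicate 1 and at -1.41 and -1.24 in AZ replicate 2. The MAP kinase phosphatases and relatives of the DUSP family were lower (19 of 22, -0.34), and MAGE genes were higher in both AZ tissues (14 of 15, 0.43 and 0.50). These directions held under the 4 other scalings and value tables tried.

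The tests in the following 3 paragraphs were chosen after the results they bear on were seen, except that leaving out AZ replicate 2 was set before the data were examined and its use as a test of the IL-17A-induced pattern was chosen afterwards. Standard errors are over genes, which are not independent replicates. AZ replicate 2 had low late differentiation genes, -1.44 ± 0.09 (SE) relative to AZ replicate 1. A smaller epidermal share of its RNA would have lowered genes made only by keratinocytes alike. Keratinocyte keratins differed by -0.64 ± 0.16, which argues against it as the whole cause and leaves a part in it open. Basal keratinocyte genes differed by -0.0401 ± 0.12, but KRT14, their brightest, was 9.07 in AZ replicate 1 and 8.29 in AZ replicate 2. That list was not checked for genes that dermal cells also express, so it cannot decide. A loss of bright signal on its array is argued against by 10000 random lists matched on brightness, which had a mean of -0.12 and a lowest value of -0.46. A tissue with a less mature upper epidermis, or an uneven response to AZ, may account for it and stays open, since 1 tissue shows it.

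Matrisome and dermal fibroblast genes were higher in both AZ tissues. A larger dermal share of the RNA would raise fibroblast genes outside the matrisome as well, and these 15 were all higher, by 0.42 ± 0.06 (SE), VIM among them at 0.72. It would also lower keratinocyte keratins, and these had -0.18 ± 0.11, with 0.14 in AZ replicate 1 and -0.50 in AZ replicate 2, so dermal share stays open. An induction of matrix genes beyond other fibroblast genes was not settled either, the matrisome members of the fibroblast list exceeding its other members by 0.10 ± 0.09. For slide and scan, 0 slides held both groups, so they and AZ treatment cannot be told apart.

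IL-17A-induced genes were lower in both AZ tissues. A smaller epidermal share would lower them no more than other keratinocyte genes, and they lay below basal keratinocyte genes by a mean of -0.353 ± 0.14 (SE). The basal list has the limit given above. That gap was -0.19 ± 0.13 in AZ replicate 1 and -0.52 ± 0.20 in AZ replicate 2, and the gap to keratinocyte keratins -0.61 ± 0.09 and -0.34 ± 0.23, so it did not exceed 2 SE for both marker sets in either tissue and epidermal share stays open. The low differentiation genes of AZ replicate 2 are argued against as the whole cause by the shift of -0.51 without that tissue. Slide and scan (0 slides held both groups) cannot be told apart from a response to AZ, so a lower expression of IL-17A-induced genes under AZ stays a hypothesis.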
